A study of Mus musculus with 12 samples.

How the data were processed

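Total RNA of the thoracic aorta of 12 male C57BL/6 mice, 5 nontransgenic and 7 transgenic littermates, was extracted with Trizol and purified on a column, per the labels' protocols. About 50 ng per mouse went through a NuGen amplification in 2 steps to biotin-labelled fragments, which were hybridised to Affymetrix mouse exon arrays of the 1.0 ST design. The deposited values are on a log2 scale, as from RMA, a method that corrects background, normalizes across arrays and summarises probes. Per the submitters' processing notes, Affymetrix Power Tools, RMA and the mm9 build were used. The versions, the class of probe sets and any filter are not given in the sources used here. RMA shrinks differences of dim genes towards 0, and amplification from a small input can add variation between arrays that the groups do not explain.

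The deposited table held 101175 rows and no missing value, and 0 columns of other samples. Array medians and upper quartiles were computed from these rows. Scanner files, detection calls and exon-level rows were not used here, so exon usage, planned only for exon-level rows, is not reported. Background was described by 919 olfactory and vomeronasal receptor genes, which most tissues do not express: their 95th percentile of the mean was 5.18. The number of arrays, not a read depth, limits the precision.

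Rows were named from the platform annotation. Of these, 22754 had 1 gene symbol, 1522 had several and were not named, and 76899 had none there. By Entrez ID, 22245 of the rows with 1 symbol were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Because that assembly differs from mm9, it was used for names, chromosomes and gene order only, and no coordinates are given. The Entrez ID of 1110064A23Rik was not in that table. For each of 19687 genes the row with the highest mean over all arrays was used; 2224 genes had more than 1 row.

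The planned comparison was P467L minus nontransgenic in limma 3.58.1 (R 4.3.3), with lmFit and eBayes over all 12 arrays and no covariate, and Benjamini-Hochberg adjustment over the genes tested. A gene was said to have risen or fallen at an adjusted p under 0.05. Errors given after ± are SE for log2 differences and SD for levels. Each array is 1 mouse.

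Before the data were examined, 26 gene lists were fixed, 16 of pathways and 10 of cell types, with 616 entries. Of these, 535 were measured, 25 lay on rows shared with another gene and 56 had no row named here. Some entries, Rhobtb1 and Rgs5 among them, came from published work on this mouse line, which may have used these same arrays. The 25 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists. No list passed with an estimated correlation or with fry's one-way test. A cell type score was the mean over a list of each value minus the gene's mean, compared by an exact two-sided permutation test over all 792 splits into 5 and 7, whose smallest p is 0.00126.

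Genes were named by a rule also fixed then: Pparg, the 10 largest differences in each direction among genes past the threshold, the 2 members of each list with the smallest p (4 where the list passed camera), and 12 genes chosen in advance (among them Rhobtb1, Rgs5, Cul3, Kcnmb1, Fabp4, Cd36, Ucp1, Adipoq and Nos3). It gave 85 genes, 28 of them past the threshold. Genes outside it are said to have been named after their values were seen. The result of 1 pathway list, with some of its members, is not reported here.

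The replicate numbers 1 to 5 occur in both groups. Arrays of the same number deviated together from their group means, with correlations over genes between 0.227 and 0.398 for all 5 numbers, so the numbers were taken to pair the arrays. This rests on the data, since the labels do not say what the numbers mark, and the own number was the best partner for 3 of 5 arrays. Nontransgenic replicate 1 correlated best with P467L replicate 2, and nontransgenic replicate 4 with P467L replicate 5. Positive correlations of equal numbers thus do not by themselves show pairing. The fit with the number as a block is given where it changes a call. In that fit the P467L arrays without a partner carry no information on genotype, so it rests on the 5 pairs.

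Alternatives fixed before the data were examined were the block, leaving out each array, quantile normalization, subtracting array medians, an adipose marker covariate, the brighter genes alone, trended and robust variances, array weights, all rows, the mean over a gene's rows, an adjusted p under 0.1, an unmoderated test, and medians in place of means for scores. Added after seeing the data were each array's upper quartile as a covariate, the arrays without the 3 least correlated with the rest (nontransgenic replicate 2 and P467L replicates 1 and 2) and, as values without a test, differences within the dimmer and the brighter arrays. The latter decide nothing for genes called on the same arrays and are not reported. The 32 splits that swap genotypes within the replicate pairs were also added, each fitted without and with the block. Intervals in the closing section come from inverting the permutation test at the 95% level, approximate where a covariate was fitted. Correlations were tested with 100000 permutations, and gene order with 10000 random gene sets.

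The fit was tested on simulated data for this comparison, 19687 genes in 5 against 7 arrays with 200 genes changed. It recovered 50% of genes changed by 0.5 log2 units, 94% at 1 and 100% at 2 and at 4, with 5 false calls. With no gene changed it made 1 call. The simulated noise was normal and independent between genes and arrays, whereas the real arrays share an intensity gradient. These rates therefore need not hold for the real data.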

Results

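Gene expression was measured in the thoracic aorta of 12 male mice, 1 array per mouse and none pooled. The 7 transgenic mice expressed the human P467L mutant of PPARγ, a dominant-negative form of this ligand-activated nuclear receptor, in vascular smooth muscle under the smooth muscle myosin heavy chain promoter. The other 5 mice were their nontransgenic littermates, and all were on the C57BL/6 background. The comparison asks which aortic genes differ when PPARγ signalling is interfered with in the muscle of the vessel wall. The values were log2 intensities from Affymetrix mouse exon arrays (the 1.0 ST design) for 101175 rows, of which 19687 genes were tested. Array medians lay between 4.74 and 4.79, and upper quartiles between 6.10 and 6.38. The number of arrays limits the precision.

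The row for Pparg itself (6.81 ± 0.19 SD in 5 nontransgenic and 6.82 ± 0.24 SD in 7 P467L aortas) differed by 0.01 ± 0.12 (SE) on the log2 scale, less than the spread between mice. An exact two-sided permutation test over the 792 splits of the mice gave p = 0.918. Whether mouse probes of this row hybridise to the human transgene is not given in the sources used here, so the row does not check the labels.

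P467L aortas differed from nontransgenic aortas in a small set of genes, 23 higher and 25 lower. Tnnc1, the troponin C of cardiac and slow skeletal muscle, had the largest rise among the 19687 named genes, from 5.71 ± 0.89 (SD, n = 5) to 9.95 ± 0.45 (SD, n = 7). Its log2 difference was 4.24 ± 0.34 (SE; limma adjusted p = 0.000197). Tnnt2, cardiac troponin T, rose by 0.82 ± 0.09 from a nontransgenic level of 5.24, just above the background level of 5.18 (limma adjusted p = 0.00192). Palld, which encodes the actin-bundling scaffold palladin, rose by 1.49 ± 0.17 (limma adjusted p = 0.00288), and its other rows differed by 1.58 and 0.71. The long noncoding RNA 5430431A17Rik rose by 1.68 ± 0.15 (limma adjusted p = 0.000262). Trem2, a receptor of myeloid cells, rose by 1.04 ± 0.10 from a nontransgenic level of 5.02, under the background level of 5.18 (limma adjusted p = 0.000607).

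The other genes with the largest rises included Sphkap, an anchoring protein of protein kinase A (1.44 ± 0.26), and Plat, tissue plasminogen activator (0.89 ± 0.16). Unc13c, a factor of synaptic vesicle priming, also passed the test, but both of its means, 3.98 and 4.96, lay under background. Acan, the proteoglycan aggrecan, rose by 0.86 ± 0.14 and Sncg, γ-synuclein, by 0.77 ± 0.12. Of the genes with the largest falls, Gabra3, a subunit of the GABA-A receptor, went from 10.43 ± 0.20 (SD, n = 5) to 9.36 ± 0.25 (SD, n = 7), a log2 difference of -1.07 ± 0.13 (limma adjusted p = 0.00432), and its other row differed by -1.27. Gabre, another subunit, differed by -0.86 ± 0.16. 2210407C18Rik differed by -1.25 ± 0.21, Sytl5, a synaptotagmin-like protein, by -1.14 ± 0.20 (other row -1.11), and 1110064A23Rik by -1.005 ± 0.15. Npr3, the clearance receptor of natriuretic peptides, differed by -1.004 ± 0.17. The long noncoding RNA 2010310C07Rik differed by -0.96 ± 0.15 and Cacna2d3, an auxiliary calcium channel subunit, by -0.91 ± 0.15. The P467L means of 2210407C18Rik, 2010310C07Rik and Cacna2d3, 4.94, 4.58 and 4.62, lay under background. Pkp4, a plakophilin of cell junctions, differed by -0.86 ± 0.11 and Sfrp2, a secreted modulator of Wnt signalling, by -0.79 ± 0.14.

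**Figure D1:**
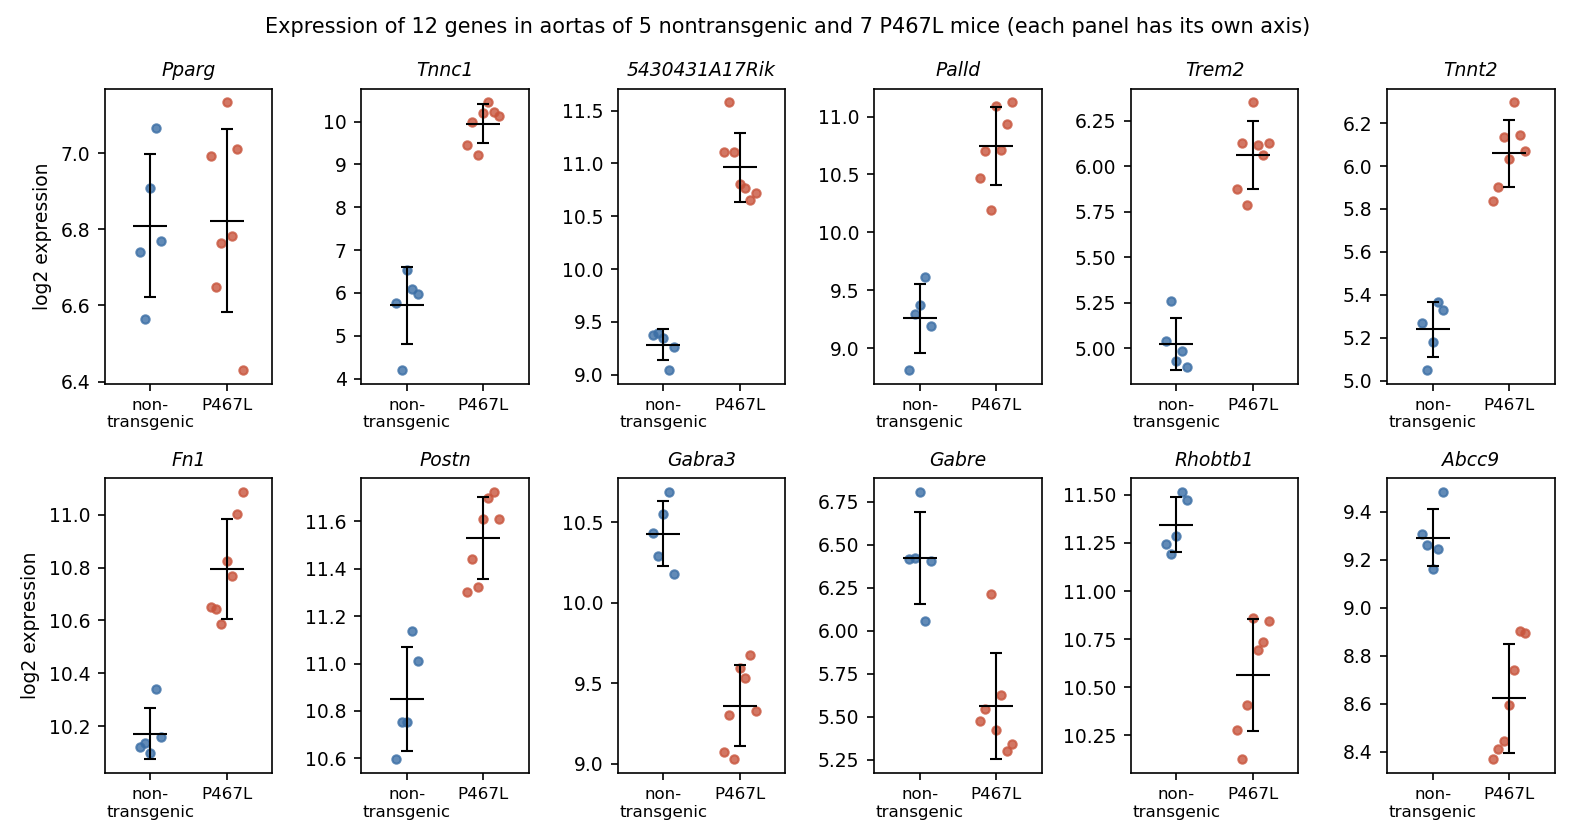
Expression (log2 intensity) of 12 genes in each aorta, with 5 nontransgenic mice in blue and 7 P467L mice in red. Each point is 1 mouse, horizontal lines are group means, bars are ± SD, and each panel has its own vertical axis. Tnnc1 lay between 4.197 and 6.54 in nontransgenic and between 9.22 and 10.4 in P467L aortas, while the groups overlapped for Pparg and Gabre.

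The 48 genes passed a Benjamini-Hochberg adjusted p under 0.05 in limma, and 10 of them differed by at least 1 log2 unit. Over all 19687 genes, the groups did not overlap in 143 (0.726%), against 0.253% by chance. At an unadjusted p under 0.05, 949 genes differed where chance alone gives 984.35. The background level of 5.18 is the 95th percentile of 919 olfactory and vomeronasal receptor genes. Both means lay above it in 34 of the 48 genes and only 1 mean in 9. Both lay under it in 5, Unc13c, Kcnj2, and, named after their values were seen, Prkg2, Rimklb and Sema3e. The count fell to 30 with the replicate number as a block, which kept 19 of the 48. The block leaves only the 5 replicate pairs to inform the comparison, so having fewer arrays may by itself lower the count. Leaving out 1 array gave between 11 and 48 genes, and leaving out the 3 arrays least correlated with the rest gave 8.

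Tnnc1, 5430431A17Rik, Palld and Trem2 passed the threshold under all 24 alternative settings with 1 value per gene, and also when all 101175 rows were tested. Of the 24 settings, 1 is the looser cut of 0.1, which any gene past 0.05 passes by construction. Tnnt2 passed under the same 24 but not among all rows (limma adjusted p = 0.0608). The rows used for the other 23 of the 28 named genes past the threshold did not pass among all rows either, though the other row of Gabra3 did (limma adjusted p = 0.00312). Of the 28, 20 lost the call when at least 1 array was left out, and the 8 that did not were Tnnc1, 5430431A17Rik, Palld, Trem2, Tnnt2, Unc13c, Gabra3 and Pkp4. Sphkap and Gabre lost it in 11 of the 12 such fits, with limma adjusted p up to 0.130 and 0.126. With the block, 12 of the 28 no longer passed it: Sphkap, Unc13c, Plat, Sncg, Sytl5, Npr3, 2010310C07Rik, Cacna2d3, Pde1c, Kcnj2, Col15a1 and Mfap5. Their limma adjusted p with the block ran from 0.0565 to 0.253, and over the 24 settings from 0.000633 to 0.253. No named gene past the threshold changed direction under any setting. Of named genes that did not pass and whose further rows are not given beside their values, those rows differed by -0.12 for Fdft1, -0.06 for Hadhb, -0.18 and -0.05 for Prdm16, 0.12 for Slc4a1, 0.02 for Dnajb9 and -0.03 for Cd79a.

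Rhobtb1, which encodes a substrate adaptor of the cullin-3 ubiquitin ligase, was lower in P467L aorta. Its level was above background in both groups, 11.34 ± 0.14 (SD, n = 5) against 10.56 ± 0.29 (SD, n = 7), and fell by 0.78 on the log2 scale (SE 0.13; limma adjusted p = 0.0320). Its other row fell by 0.91 on the log2 scale. Cul3, cullin-3 itself, differed by -0.09 ± 0.12 and did not pass the test. Rhobtb1 was among the genes chosen in advance from published work on this mouse line. Whether that work used these same arrays is not given in the sources used here. The call is therefore not independent support for it. It passed the threshold in 13 of 24 settings (limma adjusted p between 0.000636 and 0.124) and not among all rows (0.274). Leaving out any 1 of the 5 nontransgenic arrays, or P467L replicate 1, 3, 5 or 6, ended its call (limma adjusted p = 0.0901, 0.0513, 0.0821, 0.105 and 0.0948, and 0.0604, 0.0586, 0.0604 and 0.0577).

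Extracellular matrix genes had 3 of 27 measured members past the threshold, all higher. As a list they passed camera upward (adjusted p = 0.0299), but not with an estimated correlation (adjusted p = 0.725) or with the replicate block (0.0866), and in 13 of 23 settings. Fn1, fibronectin, rose by 0.62 ± 0.10, Postn, the matricellular protein periostin, by 0.68 ± 0.11 and Col15a1, a basement membrane collagen, by 0.47 ± 0.07 (limma adjusted p = 0.0189, 0.0282 and 0.0183). The same 3 members passed when adjusted over the list alone. Mmp14, a membrane-bound metalloproteinase, was next at 0.18 ± 0.06 and did not pass. The mean over the list was 0.08, and the adjusted p ranged from 0.00306 to 0.725 over the settings. Leaving out nontransgenic replicate 1, 2 or 5 ended the call (adjusted p = 0.0598, 0.116 and 0.161), as did leaving out P467L replicate 3, 5, 6 or 7 (0.0594, 0.0876, 0.0809 and 0.0820).

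Ion channel genes changed both ways, with 1 of 28 measured members higher and 1 lower. Abcc9, the sulfonylurea receptor of the vascular ATP-sensitive potassium channel, differed by -0.67 ± 0.11 (limma adjusted p = 0.0282). Kcnj2, an inward rectifier potassium channel, was the higher one, with both means, 3.58 and 4.07, under background. Kcnj2 did not pass with the replicate block (limma adjusted p = 0.0888). Adjusted over the list alone, 2 members rose and 1 fell, the further one being Ano1, a calcium-activated chloride channel named after its values were seen (0.47 ± 0.11). Kcnmb1, the smooth muscle subunit of the calcium-activated potassium channel, differed by -0.06 ± 0.17. The list as a whole did not pass camera (adjusted p = 0.0984).

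Nitric oxide and cyclic nucleotide genes also went both ways: of 27 measured, Npr3 fell and Pde1c, a calmodulin-dependent phosphodiesterase, rose by 0.51 ± 0.09 from 4.68, under background, to 5.19. Neither passed with the replicate block (limma adjusted p = 0.0888 and 0.223). Adjusted over the list alone, 1 rose and 2 fell, the further one being Npr1, a natriuretic peptide receptor named after its values were seen (-0.31 ± 0.08). Nos3, endothelial nitric oxide synthase, differed by 0.14 ± 0.10. The list's camera adjusted p was 0.926, with a mean of -0.01 and a median of 0.03. Of 25 vasoconstrictor receptor and G protein signalling genes none passed over all genes. Adjusted over the list alone 1 fell, Edn1, the endothelin precursor, at -0.87 ± 0.22 (limma adjusted p over all genes = 0.232, and 0.0352 without nontransgenic replicate 5, in a range up to 0.574). Gnaq differed by 0.30 ± 0.09 and Rgs5, a regulator of G protein signalling, by -0.17 ± 0.13 (other row -0.53). That list's camera adjusted p was 0.831, with a mean of 0.01 and a median of -0.02.

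Smooth muscle contractile genes showed no change past the threshold in 21 measured members (camera adjusted p = 0.250). Des, desmin, came closest at 0.61 ± 0.11 (limma adjusted p = 0.0510) and was the 1 member higher when adjusted over the list alone. It passed over all genes in 11 of 24 settings (limma adjusted p from 0.0235 to 0.159). Itga8 differed by -0.24 ± 0.10. None of 25 PPAR target genes passed, over all genes or adjusted over the list alone. Their mean difference was -0.04 (camera adjusted p = 0.583), with Fabp3 at 0.20 ± 0.11, Hadhb at -0.34 ± 0.21, Fabp4 at -0.21 ± 0.17 and the fatty acid transporter Cd36 at -0.11 ± 0.21.

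The other pathway lists described here held no member past the threshold, over all genes or adjusted over the list alone, and none passed camera. The camera adjusted p was 0.359 for 25 inflammatory NF-κB targets, where Il1r1 differed by 0.28 ± 0.13 and Vcam1 by 0.34 ± 0.17. It was 0.583 for 17 interferon-response genes, with Irf7 at 0.47 ± 0.18 (other row -0.02) and Oasl2 at 0.15 ± 0.11. It was 0.831 for 21 oxidant and antioxidant genes (mean 0.02, median -0.02), with Sod3 at 0.28 ± 0.09 and Cybb at 0.25 ± 0.16. For 33 oxidative phosphorylation genes it was 0.359 (Cox5b -0.31 ± 0.13, Ndufb3 -0.18 ± 0.13) and for 18 circadian clock genes 0.583 (Tef -0.31 ± 0.14, Per3 -0.31 ± 0.24). For 28 cell cycle genes it was 0.586 (Rrm2 0.60 ± 0.17, Mcm6 0.41 ± 0.15) and for 16 cholesterol synthesis genes 0.831 (Stard4 -0.23 ± 0.08, Fdft1 -0.37 ± 0.16). For 25 immediate-early genes it was 0.548 (Gadd45b -0.29 ± 0.15, Fos -0.34 ± 0.19) and for 21 heat shock and unfolded protein genes 0.480 (Hspa1a -0.61 ± 0.23, Dnajb9 -0.20 ± 0.09). Only 4 of the 28 cell cycle and 7 of the 17 interferon-response genes were above background in nontransgenic aorta, which limits both results. Rrm2 lay under background in both groups (3.74 in nontransgenic and 4.33 in P467L).

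Markers of the other cell types that a dissected aorta can hold were compared next. Perivascular fat did not separate the groups: the adipocyte score (17 markers) differed by 0.00 and the brown adipocyte score (13 markers) by -0.04, with exact p = 0.980 and 0.860. Adipoq differed by -0.08 ± 0.18 and Ucp1, the uncoupling protein of brown fat, by 0.25 ± 0.51. Slc2a4 (-0.18 ± 0.08), Pck1 (-0.28 ± 0.14), Prdm16 (-0.37 ± 0.16) and Kcnk3 (0.17 ± 0.10) did not pass either. None of the 9 cell type scores passed an exact permutation test after adjustment. The lowest p was that of the endothelial score, 0.07 higher in P467L (exact p = 0.0278, adjusted p = 0.250). Among 20 endothelial markers none passed over all genes. Adjusted over the list alone, the tight junction gene Cldn5 rose (0.52 ± 0.13, from 5.06, under background) and the sialomucin gene Emcn fell (-0.88 ± 0.17). Emcn passed over all genes in 5 of 24 settings (limma adjusted p from 0.0323 to 0.234).

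Skeletal muscle markers passed camera upward (adjusted p = 0.00985), with 0 of 17 members past the threshold, over all genes or adjusted over the list alone. The adjusted p was 0.918 with an estimated correlation. The shift came from 1 array: P467L replicate 4 scored 2.17, while the other 6 P467L arrays lay between -0.30 and -0.14. Without it the list's mean was -0.02 (camera adjusted p = 0.658), without nontransgenic replicate 2 the adjusted p was 0.0518, and among the brighter genes alone 0.0836, in a range of 0.000210 to 0.934 over 23 settings. Myoz1 differed by 0.27 ± 0.11, Neb by 0.70 ± 0.38, Casq1 by 0.34 ± 0.23 and Actn3 by 0.28 ± 0.19. The score difference was 0.32 (exact p = 0.751). Of 12 cardiac muscle markers only Tnnt2 passed, over all genes and adjusted over the list alone (camera adjusted p = 0.119; score difference 0.11, exact p = 0.154), and Nppb, a natriuretic peptide, differed by -0.24 ± 0.10.

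Of 19 fibroblast markers Mfap5, a microfibril protein, fell by 0.65 on the log2 scale (SE 0.10; limma adjusted p = 0.0183). Adjusted over the list alone 2 fell, the other being the proteoglycan Fmod, with both means, 4.90 and 4.46, under background. Over all genes Fmod passed only without nontransgenic replicate 5 (limma adjusted p = 0.0483, in a range up to 0.858). The list's camera adjusted p was 0.831, its mean -0.02 and its median 0.04 (score exact p = 0.783). Of 20 macrophage and leukocyte markers none passed, H2-Aa differed by 0.26 ± 0.18 and C1qc by 0.12 ± 0.08, and the score difference was 0.08 (exact p = 0.457). That list's camera adjusted p was 0.0984, against 0.000557 with the replicate block, and with an estimated correlation the adjusted p was 0.918 without and 0.525 with the block, in a range of 0.000101 to 0.934. It passed without nontransgenic replicate 3 (0.000101) and without P467L replicate 7 (0.00632). No member passed of 15 lymphocyte markers (camera adjusted p = 0.0984; score exact p = 0.278; Cd79a 0.22 ± 0.11, Cd4 0.14 ± 0.08), nor of 17 nerve and Schwann cell markers (camera adjusted p = 0.583; score exact p = 0.683; Nefl 0.28 ± 0.13, Scn7a -0.18 ± 0.14). In nontransgenic aorta 0 of the 15 lymphocyte and 7 of the 17 nerve markers were above background. The lymphocyte values therefore cannot show whether lymphocyte content differed. The erythroid list had 4 measured members and was not tested (Slc4a1 0.19 ± 0.08, Alas2 0.19 ± 0.25).

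**Figure D2:**
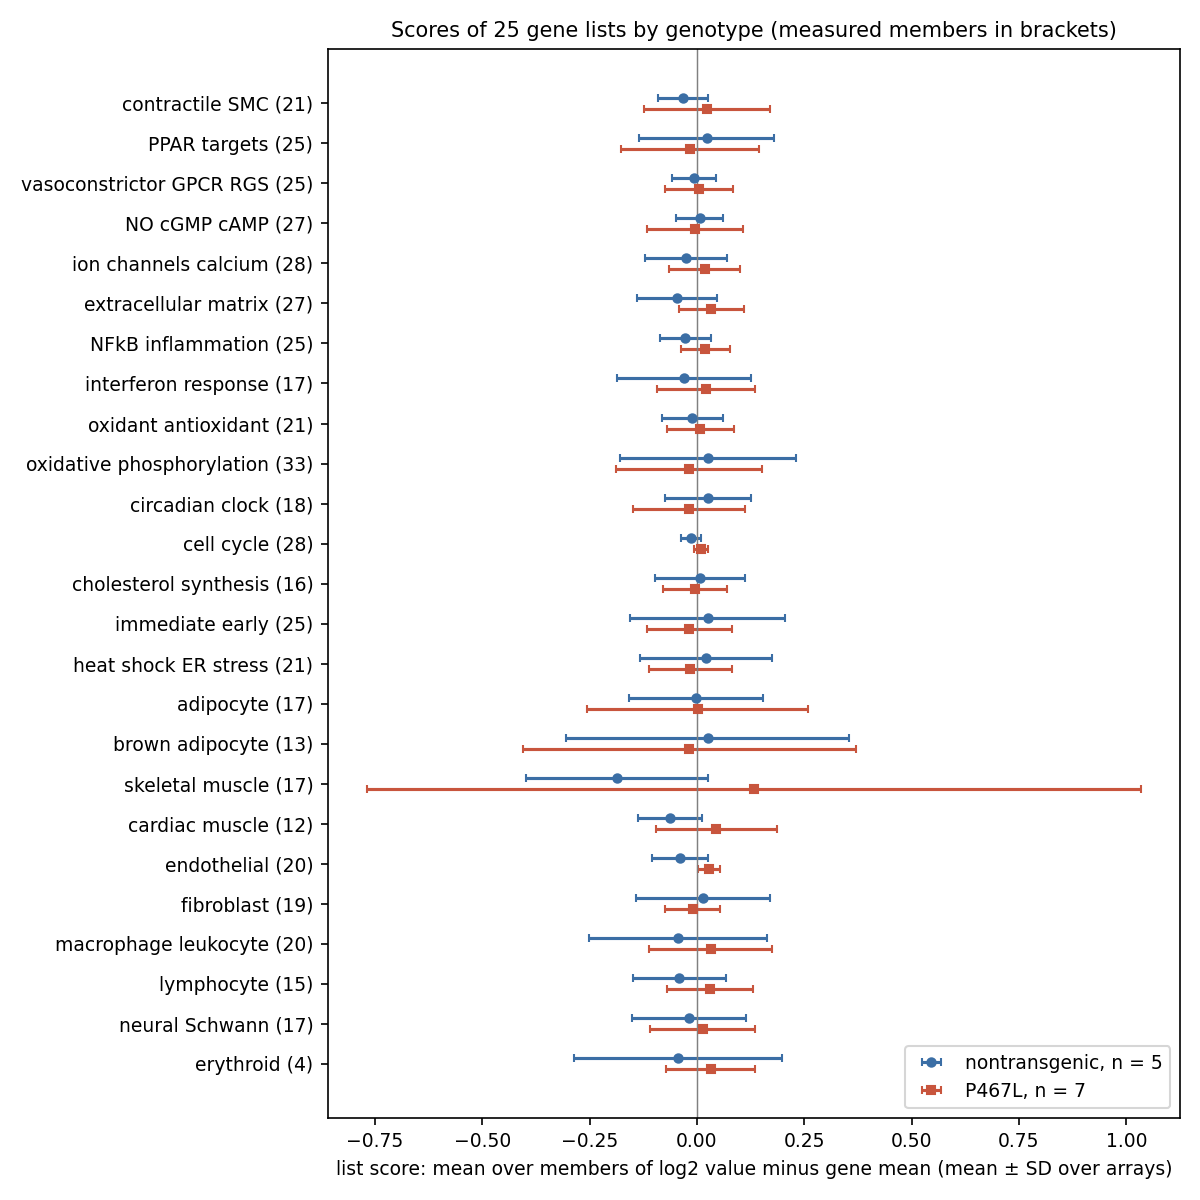
Mean score (log2 units, mean over list members of the value minus the gene's mean) of each of 25 gene lists, as group mean ± SD over 5 nontransgenic (blue circles) and 7 P467L arrays (red squares), with the measured members in brackets. The skeletal muscle list has by far the widest bar, an SD of 0.902 in P467L, set by 1 array.

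The arrays also differed along an intensity gradient that was present within both groups. In each of the 5 replicate pairs, however, the P467L array had the lower upper quartile, so within pairs the gradient ran with genotype. The permutations of the correlations below ignored the pairs. The first principal component of the deviations from the group means held 35.1% of the variance. Each array's upper quartile fell as its median over olfactory and vomeronasal receptor genes rose (r = -0.883, permutation p = 7e-05, adjusted p = 0.00014; Spearman coefficient -0.748, permutation p = 0.0073; n = 12). Without the 2 arrays farthest from the median upper quartile r was -0.920. The upper quartile showed no such relation with the mean adipose marker score (r = -0.0742, permutation p = 0.82, adjusted p = 0.82; Spearman coefficient -0.168, permutation p = 0.6; r = -0.0329 without 2 arrays), the other of 2 relations computed. With the upper quartile as a covariate, a setting added after seeing the data, 71 genes were higher and 35 lower, and all 48 genes were kept. The ion channel and macrophage lists then passed camera (adjusted p = 0.0225 and 0.0445), but not with an estimated correlation (adjusted p = 0.853 and 0.946 with the covariate, 0.725 and 0.918 without it). Of the named genes not past the threshold in the planned comparison, Vcam1 (0.46; limma adjusted p = 0.0118), Mcm6 (0.51; 0.0403) and Des (0.61; 0.0463) passed with the covariate. Des also passed in other settings. Over 24 settings the adjusted p of Vcam1 ran from 0.0118 to 0.99998 and that of Mcm6 from 0.0403 to 0.99998, and this was the only setting in which either passed.

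**Figure D3:**
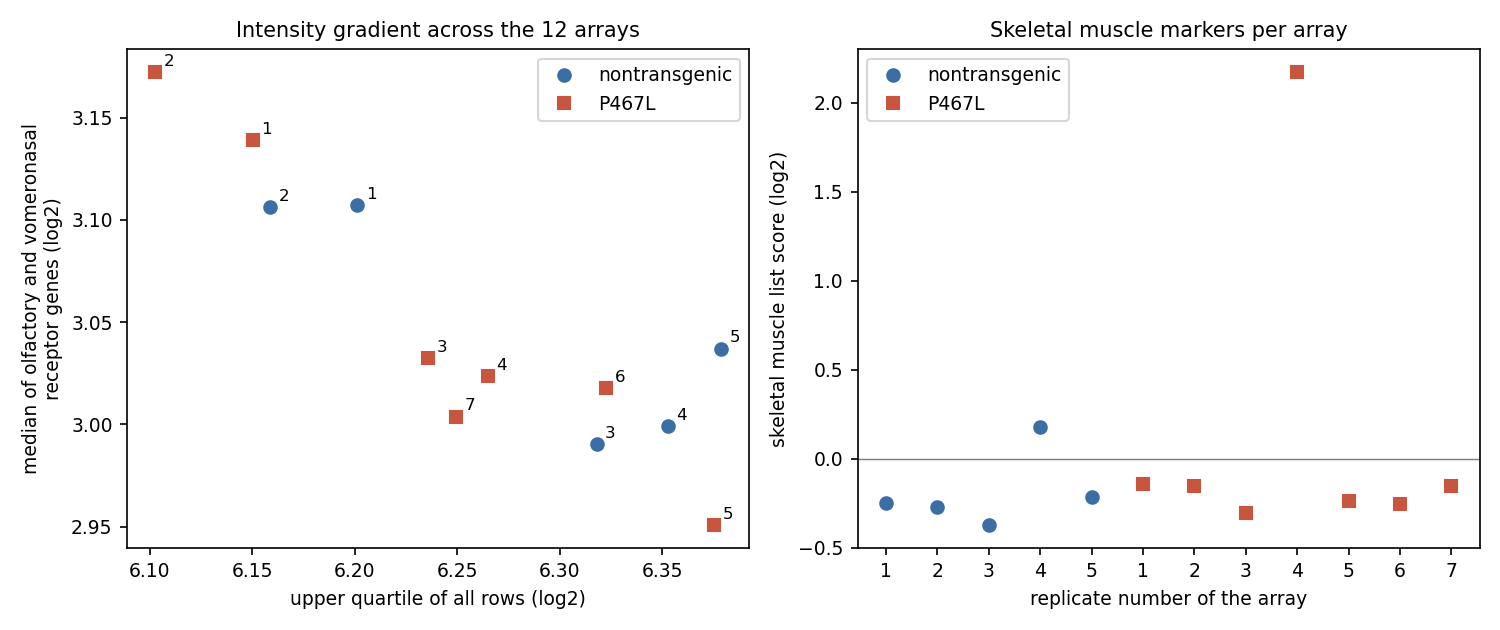
Left, the median log2 intensity of olfactory and vomeronasal receptor genes against the upper quartile of all rows, 1 point per array, numbered by replicate. Right, the skeletal muscle marker score (log2 units) of each array by replicate number, where P467L replicate 4 scored 2.17 and nontransgenic replicate 4 scored 0.179.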

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

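The tests of splits within the replicate pairs, of the intensity gradient on the gene count and on the troponins, of skeletal muscle and of the X-linked neighbours were chosen after the results were seen. The skeletal muscle test replaced an undecided one on the score difference, 0.32, and the gradient test of the troponins was first run on Tnnc1 alone, where the difference was 4.42. The test of the X-linked neighbours replaced one on all 8 of them, with a mean of 0.0757, because 5 of the 8 lay under background in nontransgenic aorta and could not be seen to fall.

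Of 100 splits of the mice drawn from the 792 into 5 and 7, the real one included and the replicate pairs ignored, 2 gave at least the 48 genes of the real split. The highest other gave 1668 and parted 1 of the 5 pairs. It set nontransgenic replicates 1 and 2 and P467L replicates 1, 2 and 4 against the rest, which points to a structure of the arrays. Apart from P467L replicate 4 (6.26), these arrays had the lowest upper quartiles (6.20, 6.16, 6.15 and 6.10). That split thus mostly followed the intensity gradient. Of all 32 splits that part the 5 pairs and leave the 2 unpaired P467L arrays in place, only the real one reached 48 genes. The highest other gave 0. Chance is thus only narrowly disfavoured, at 0.0312 (1 of 32), the smallest share these splits can give. This holds only if the replicate numbers mark pairs, which the labels do not say and the correlations do not show by themselves. With the block the 16 distinct splits are too few for a share under 0.05 (30 genes in the real one, at most 1 in another). With the upper quartile as a covariate all 48 genes stayed past the threshold, which argues against the intensity gradient as the whole cause, but how many genes differ stays open, since the replicate block and leaving out arrays lower the count.

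The rise of Tnnc1 and Tnnt2, on average 2.53 (95% interval 2.10 to 3.04; Tnnt2 not past the threshold among all rows), could come from heart or skeletal muscle left on the vessel. Both genes were picked for their calls on these same arrays, so the interval may overstate the rise. The 9 other cardiac markers with a comparably low baseline, such as Myl2, Myl3 and Nppa, differed by 0.0535 on average (-0.14 to 0.254), far under the 1 log2 unit set for cardiac tissue. Of the 12 cardiac markers, 7 were above background in nontransgenic aorta and 2 stood on another list too. With the skeletal muscle score as a covariate the mean rise was 2.51 (2.04 to 3.05), and with the upper quartile 2.64 (2.32 to 3.01). Tnnc1 (4.24) outweighs Tnnt2 (0.82) in this mean, so the mean decides nothing for Tnnt2. Taken singly with the upper quartile as a covariate, Tnnc1 rose by 4.42 and Tnnt2 by 0.87. The skeletal muscle score was raised in P467L replicate 4 alone (2.17), so that score as a covariate could hardly lower a rise seen in all 7 P467L arrays. In the other P467L arrays the score lay between -0.30 and -0.14, within the nontransgenic range. Expression in the transgenic vessel wall itself and an effect of where the transgene inserted stay open as hypotheses, and neither was tested.

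Gabre and Gabra3, GABA-A receptor subunit genes near each other on the X chromosome, were both lower, but the call of Gabre was lost in 11 of the 12 fits without 1 array (limma adjusted p = 0.0586 to 0.126) and kept in 10 of 24 settings (0.00551 to 0.318). With Gabrq beside them, named after its values were seen (-0.38 ± 0.16, not past the threshold and under background in both groups), the mean was -0.77 (95% interval -0.9998 to -0.571). Gabre and Gabra3 were picked for their calls on these same arrays, so this interval may overstate the fall. Of the 4 named genes on each side, the 3 above background, Prrg3, Cetn2 and Nsdhl, differed by -0.00255 on average (-0.218 to 0.213), which argues against an equal fall of the expressed genes around them, and with the upper quartile as a covariate the mean of the 3 was -0.773 (-1.01 to -0.563). Among all called genes 3 pairs, Gabre with Gabra3 included, lay at most 2 named genes apart, against 0.34 on average in random sets. A share of 0.0045 of random sets held as many. The other pairs, Epha1 with 2010310C07Rik and Rimklb with Mfap5, lay on chromosome 6. This share therefore does not test the pair of Gabre and Gabra3 alone. A fall of the subunit genes alone may be biological, as a hypothesis that no test here decided, and transgene expression and insertion were not told apart.

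Single arrays that stood far from the rest of their group were found in 8 of 188 combinations of a gene or score with a group. This is no more often than chance, which gives about 1 in 20. P467L replicate 4 was the highest of its group for Neb (7.49), Actn3 (6.37) and the skeletal muscle score (2.17). Nontransgenic replicate 4 was the highest of its group for the same score (0.179) and for Fn1 (10.3). P467L replicate 3 was the highest of its group for Gabre (6.22), nontransgenic replicate 2 the lowest for Fdft1 (8.61), and P467L replicate 7 the lowest for Adipoq (8.77).

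Rows without a gene name took no part in the comparison of genes. When all 101175 rows were tested, 4 of 76899 such rows passed, 2 higher and 2 lower. Row 6821893 was higher in P467L by 5.12 (3.63 in nontransgenic, which is under background, and 8.75 in P467L; limma adjusted p = 4.2e-06), and row 6853766 by 2.11 (5.81 and 7.93; 3.01e-05). Row 6781275 differed by -2.99 (7.98 and 4.99; limma adjusted p = 0.0120) and row 6906417 by -1.85 (5.48 and 3.63; 0.0408), both with a P467L mean under background. Their genes were not analysed here.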

How the results depend on the processing

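The upper quartile covariate and the set of 9 arrays were added after seeing the data. The count of 48 genes (23 higher, 25 lower) moved by over 1.5 times to 30 (14 and 16) with the replicate block and 74 (42 and 32) after quantile normalization. It moved as far to 15 (7 and 8) with the unmoderated test, 106 (71 and 35) with the upper quartile covariate and 8 (6 and 2) in 9 arrays. Over all rows 9 rows passed (6 higher and 3 lower), a count of rows and not of genes, since 4 of them had no gene name. Leaving out 1 array gave 11 to 48 genes, 7 to 30 higher and 4 to 18 lower: 11, 37, 18, 13 and 22 without nontransgenic replicates 1 to 5, and 37, 29, 48, 22, 24, 24 and 30 without P467L replicates 1 to 7. Testing all rows raises the number of tests, and leaving out arrays lowers that of samples. The block also lowers the number of arrays that inform the comparison, since P467L arrays without a partner then carry no information on genotype. How much of the fall to 30 this explains was not tested, nor was the cause for the other settings. The count stayed within 1.5 times, between 42 and 63, under the 7 other settings. Of the 48 genes, 19 were kept with the block, 43 after quantile normalization, 14 with the unmoderated test and 7 in 9 arrays. The Pparg difference, 0.01, changed sign without passing any test with array weights (-0.0213), in 9 arrays (-0.0468) and when arrays were left out (-0.0477 to 0.0788).

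The number of lists passing camera, 2, became 0 with an estimated correlation, 0 with fry and 4 with the upper quartile covariate, and 1 to 4 when 1 array was left out. Lists not past the threshold otherwise passed without nontransgenic replicate 1 (lymphocyte, adjusted p = 0.0471), 2 (oxidative phosphorylation, 0.0458), 3 (endothelial, 0.0380, and macrophage) or 5 (ion channels, 0.0195, immediate-early, 0.0473, and cardiac, 0.0473), and without P467L replicate 3 (contractile, 0.0404), 4 (oxidative phosphorylation, 0.0484) or 7 (macrophage). The endothelial list passed after quantile normalization (0.0179) and the cardiac list among the brighter genes (0.0410), where the skeletal muscle list no longer did (0.0836). With the block, 2 lists passed, skeletal muscle and macrophage (camera adjusted p = 0.000210 and 0.000557). Neither passed with the block and an estimated correlation (camera adjusted p = 0.592 and 0.525). Beyond those given beside their results, the block changed no call of a named list or gene. Cell type scores stayed at 0 past the threshold under every setting run. With the block, their smallest possible exact p over 5 pairs is 0.0625, which cannot pass. Signal near background limits the 5 genes at or under the receptor percentile in both groups. It also limits the lymphocyte list, with 0 of its 15 markers above background in nontransgenic aorta.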

Other observations

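The gene positions by chromosome, and the choice to test them, came after the calls were seen. Beyond the named genes, others past the threshold, chosen after their values were seen, were the phosphatase Inpp4a (0.72) and the apolipoprotein Apod (0.59), both higher in P467L. The lower ones included the BMP receptor Bmpr1b (-0.79), the retinol carrier Rbp4 (-0.49), the phospholipase Plce1 (-0.54) and the Wnt effector Tcf7l2 (-0.50). All 6 had a limma adjusted p under 0.05.

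Fry's mixed test, which takes a list's changes in either direction, had an adjusted p under 0.05 for ion channels (adjusted p = 4.09e-05), extracellular matrix (4.7e-05), cardiac muscle (7.81e-05), fibroblast (0.00496), nitric oxide and cyclic nucleotide (0.00538), endothelial (0.00699) and cell cycle genes (0.0454). This test does not compare a list with other genes, and it does not say which members differ. Over all genes, 0 of 28 cell cycle and 0 of 20 endothelial members passed, and 4 of the 28 cell cycle genes were above background in nontransgenic aorta.

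The intensity gradient across arrays may reflect background signal. The arrays' upper quartile moved against the receptor median with r = -0.883, which is consistent with it, but normalization across arrays ties the dim and bright ends of each array together, so this relation does not tell background apart from other causes such as amplification yield. No biological explanation was tested.

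Of 47 called genes placed on a chromosome, 8 lay on chromosome 6, against 2.62 for an even spread over the genes tested. A share of 0.0363 of 10000 random gene sets had a chromosome at least as over-represented, so chance placement is only narrowly disfavoured. Of the 3 close pairs, 2 lie on that chromosome (Epha1 with 2010310C07Rik, Rimklb with Mfap5), so the tests overlap. Linked differences between the littermates, such as a segment carried along with the transgene, are a possible explanation that was not tested.

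Among genes that mark sex, all 12 arrays had low Xist (3.07 to 3.76), and Eif2s3y (6.48 to 8.04), Kdm5d (6.04 to 6.95) and Uty (7.18 to 8.31) were above background, as in the males the labels give.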
